A study of Mus musculus with 4 samples.

How the data were processed

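RNA was measured in whole uteri of C57 mice on day 4 of pregnancy, in 2 libraries labelled with the p38α genotype ff and 2 labelled dd, and the series title names wild-type and p38α knockout uteri. Per the labels' protocols, RNA was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit, and the series design text states a poly-A purification. Per the submitters' processing notes the authors used STAR, edgeR and the mm10 genome build, without versions. The read counter, the gene annotation and any use of strand are not given in the sources used here. Counting without strand cannot separate a gene from a partner on the opposite strand, and 43 of the 144 genes named by the rule below overlap an annotated gene on the opposite strand. How reads shared by near-identical genes were assigned is likewise not given, so values of immunoglobulin segments, globin genes, pseudogenes and Sprr2 genes are uncertain.

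The deposited table holds 54152 gene symbols, with whole-number counts per library, counts rescaled by the authors (a signal column, not tested here), FPKM values per the file headers, a fold (the ratio of dd over ff) and an unadjusted p-value. The series design text says RPKM where the file header says FPKM. The authors' deposited fold equalled the ratio of the group means of the rescaled counts within 0.01 on the log2 scale for 92.9% of 17572 genes with at least 50 counts. Which test gave the authors' deposited p-value is not given in the sources used here. All 54152 symbols matched GENCODE release 21 of the mouse annotation, which is on the same build, and gene positions and types were taken from it; 109 symbols occur there more than once and were placed at the first entry.

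Total counts were 32451670 and 30202955 in ff replicates 1 and 2, and 24619850 and 30868922 in dd replicates 1 and 2. A count of 3 corresponded to between 0.0901 and 0.127 CPM in these libraries. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 35.3 over 18344 genes in ff and 36.0 over 17880 genes in dd, so no library was another one sequenced again. Separate libraries from 1 RNA or 1 animal would also differ by more than that noise and are not excluded. Counting intervals of ratios and floors cover counting error only, intervals of log2 changes come from the edgeR fit, and intervals of shares of genes are exact binomial ones.

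Groups were compared with edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalisation, filterByExpr, a quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. All 4 libraries entered the fit, without a block. CPM values are counts relative to the TMM-scaled library size, as mean ± SD of 2 libraries. A fold against a group without counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval. The biological coefficient of variation was 0.185.

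Before the data were examined, 32 gene lists were fixed for pathways and cell types of the uterus and for tissues that could be carried over. Lists with at least 3 tested members (31 of them) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The genes to be named were also set by rule. They were Mapk14, then Pgr, Esr1, Ube3c, Areg, Ihh, Hand2, Lif, Ltf, Muc1 and Mki67. To these were added the 8 largest increases and the 8 largest decreases among called genes with at least 5 CPM in the higher group and no overlap between the groups, leaving out Gm and Rik loci, and up to 4 members of each list with the smallest p. Members named outside the rule, as further called members of a list or in the closing part, were chosen after their values were seen.

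Alternatives were a replicate block, each library left out in turn, DESeq2 size factors, upper quartile factors, no filter, a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, edgeR's exact test, limma-trend on log2(FPKM + 0.5), stricter thresholds and, added after seeing the data, protein-coding genes only and library size without TMM factors. With 1 library left out, the lone library of its group was assumed to vary like the other group.

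The edgeR test was tested on simulated counts for this comparison, with 200 of 18162 genes changed. It recovered 54% of 2-fold increases, 92% of 4-fold increases, 36% of decreases to a fold of 0.5 and 90% of decreases to 0.25. Over 10 simulated sets, 220 of 1645 calls (13.4%) were unchanged genes, above the nominal rate, and no gene was called when none was changed. In the simulated list test the shifted list was recovered and 1 unshifted list was called. The window scan of the closing part, on simulated calls over 15923 genes, passed in 20 of 20 sets with 20 calls crowded into 1 window and in 3 of 40 without.

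Permutation and exact tests of the closing part used Python 3.11.15 with scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.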

Results

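Gene expression was measured by RNA sequencing in whole mouse uteri on day 4 of pregnancy, in 2 libraries labelled p38α ff and 2 labelled p38α dd. The series title sets wild-type against p38α knockout uteri, so the comparison asks which transcripts differ in the uterus with p38α (the stress-activated kinase encoded by Mapk14) deleted. The libraries held between 24619850 and 32451670 counts. Labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples. Correlations of log2 CPM across genes were 0.984 between the ff replicates, 0.984 between the dd replicates, and between 0.933 and 0.954 for pairs across groups. Mitochondrial transcripts took 5.24% and 6.02% of counts in the ff libraries, and 6.97% and 5.29% in the dd libraries.

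Mapk14 (chromosome 17, 28691329 to 28748406, mm10) was not lower in the libraries labelled dd. It had 3074 and 2710 counts in the ff libraries and 2481 and 3429 in the dd libraries, or 89.7 ± 3.78 against 109.1 ± 5.79 CPM (SD, n = 2). The log2 fold change of dd over ff was 0.28 (SE 0.09), which did not pass edgeR's test (adjusted p = 0.12). The authors' deposited table gives a fold of 1.22 and an unadjusted p of 0.539 for it. Counts over the whole gene cannot show the loss of a few exons, and the deleted part of Mapk14 is not given in the labels. Every direction below therefore rests on the labels ff and dd alone, which the counts of the targeted gene do not bear out.

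Between these groups, 1554 of 18530 tested genes (8.4%) changed in edgeR's quasi-likelihood test, 838 higher and 716 lower in the libraries labelled dd. At least 2-fold differences were found for 566 of the higher and 398 of the lower genes. The genes Ltf (lactoferrin), Sprr2f and Clca1 of the estrogen response list rose. So did the keratin genes Krt8 and Krt19, the oviduct gene Ovgp1 and 79 of 162 tested immunoglobulin segments. The gland protease inhibitor Spink1, the tachykinin gene Tac2, the tachykinin receptor gene Tacr1, the interferon-inducible gene Ifi213 and the imprinted non-coding RNA H19 fell. The majority turned with the scaling: 53.9% of changed genes were higher with TMM, 47.4% with upper quartile factors (748 higher, 830 lower) and 42.4% with the library size alone (751 and 1020), which was added after seeing the data. Fewest calls were left without ff replicate 1, in a fit with 1 ff library. A lost call there does not by itself mean that the difference came from that library. Some log2 changes hardly moved, as with Gbp3 (−1.17 against −1.15 with all libraries) and Dusp23 (−1.90 against −1.89). Others shrank, as with Coch (−2.99 against −4.19) and Lrg1 (−3.25 against −4.66). Of the 81 called genes named by rule, 13 also passed without ff replicate 1, and 10 passed whichever library was left out, namely Ltf, Sprr2f, Ifi213, H19, Tek, Hba-a1, Ovgp1, Csf3, Igkv3-5 and AC165951.1.

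**Figure D1:**
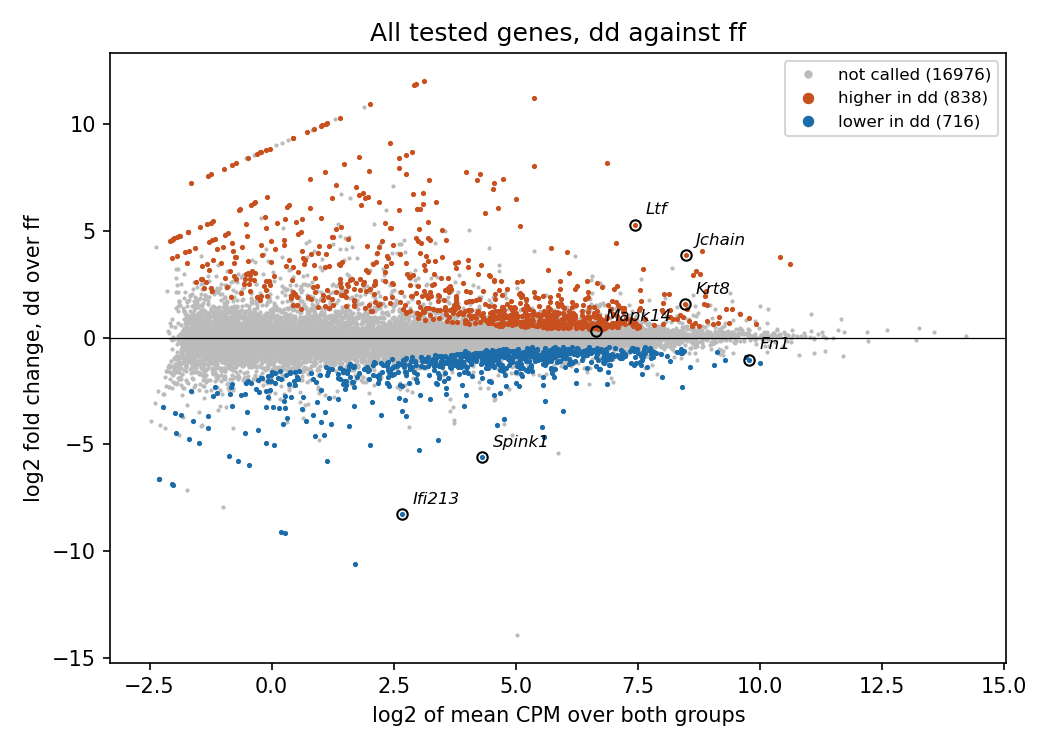
Log2 fold change of dd over ff (vertical axis) against the log2 of the mean CPM over both groups (horizontal axis), 1 point per tested gene, with genes called higher in dd in orange (838), lower in blue (716) and others in grey. Mapk14 lies near 0 at 0.28, while Ltf and Jchain lie above and Ifi213, Spink1 and Fn1 below.

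Among the largest decreases, Ifi213 had 412 and 408 counts in the ff libraries and 1 in each dd library, a ratio of 343.1 (95% counting interval 94.7 to 2838). Spink1 fell from 38.9 ± 31.5 to 0.812 ± 0.168 CPM, with a log2 change of −5.59 (adjusted p = 0.0292), and its call was lost without dd replicate 1 (adjusted p = 0.078) or dd replicate 2 (adjusted p = 0.0948). Log2 changes were −5.28 for Tacr1, −5.01 for Tac2, −4.66 for Lrg1, −4.19 for Coch, −4.09 for Cyp1b1 and −3.81 for H19. In Spink1, Tacr1, Tac2, Lrg1 and Coch the ff libraries themselves differed, as with 4985 and 1085 counts of Lrg1. Without ff replicate 1 the log2 changes were −4.36 for Spink1, −4.32 for Tacr1, −3.95 for Tac2, −3.25 for Lrg1 and −2.99 for Coch, and without ff replicate 2 they were −6.25, −5.86, −5.61, −5.36 and −4.84. For Cyp1b1, with 25 and 128 counts in dd, the log2 change was −3.44 without dd replicate 1 and −5.44 without dd replicate 2. Tacr1, Tac2 and Cyp1b1 did not pass without ff replicate 1 (adjusted p = 0.0504, 0.0506 and 0.0851), and Tacr1, Tac2, Lrg1 and Coch did not pass without dd replicate 1 or dd replicate 2 (adjusted p between 0.0703 and 0.119). The largest increases were immunoglobulin genes and AC165951.1, an antisense locus on chromosome 17 (30920338 to 30963220). AC165951.1 had no count in ff and 370 and 440 in dd, at least 322.7-fold higher against a floor of 3 counts over the group. That bound was 156 without ff replicate 1 and 166.7 without ff replicate 2. If counting ignored strand, which is not given, the reads of AC165951.1 cannot be told from those of the genes it overlaps on the opposite strand.

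Genes that respond to estrogen rose as a list in the libraries labelled dd, with 6 of 16 tested members higher and 1 lower (7 and 1 adjusted over the list alone). The median log2 change was 0.94 (camera adjusted p = 0.00198; adjusted p = 0.607 with an estimated correlation). Ltf went from 8.84 ± 6.39 to 340.3 ± 92.2 CPM (SD, n = 2), a 38.6-fold increase (log2 5.27, SE 0.609, adjusted p = 0.0238), which was 25.5-fold without ff replicate 1 and 78.4-fold without ff replicate 2. Clca1 rose 90.2-fold from 0.711 ± 0.538 to 63.8 ± 31.4 CPM. Its fold was 189.8 without ff replicate 2, 59.1 without dd replicate 1 and 58.1 without ff replicate 1, when it did not pass (adjusted p = 0.0563). Sprr2f rose 21.5-fold, and the mucin gene Muc1 rose 1.87-fold from 59.2 ± 12.3 to 110.9 ± 3.17 CPM. Padi4 and Ramp3 were the other increases, and epithelial markers were higher in the same libraries (median 1.11). Igf1, the growth factor made in uterine stroma, fell from 387.9 ± 58.5 to 180.8 ± 17 CPM (log2 −1.10). Without dd replicate 1 the list no longer passed (adjusted p = 0.0812), and leaving out ff replicate 1, ff replicate 2, dd replicate 1 or dd replicate 2 left 3, 5, 4 and 5 members higher. Muc1 kept its call only without ff replicate 2, its adjusted p being 0.0813, 0.0879 and 0.106 without ff replicate 1, dd replicate 1 and dd replicate 2.

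The progesterone receptor gene Pgr was slightly higher in dd, at 214.5 ± 2.59 against 152.6 ± 2.23 CPM (log2 0.49, SE 0.085, adjusted p = 0.0392). Its call was lost without any 1 library (log2 0.48 to 0.51), with the replicate block, and with library size as the scaling (edgeR adjusted p = 0.0544 for library size). Its co-chaperone gene Fkbp4 rose 1.59-fold (log2 0.667). Fkbp4 likewise lost its call without any 1 library (log2 0.587 to 0.747). Esr1, the estrogen receptor gene, had a log2 change of 0.35 that did not pass (adjusted p = 0.106). Of 13 receptor and cofactor genes 2 were higher (3 adjusted over the list alone), and the list had a camera adjusted p of 0.174. Genes that respond to progesterone did not shift in 1 direction as a list (median −0.22, camera adjusted p = 0.407). Of 26 members 1 was higher and 2 lower (3 and 4 adjusted over the list alone), or 3 and 1 with the replicate block. By an unadjusted p under 0.05, 5 were higher and 9 lower, and DESeq2 called 4 higher and 7 lower. Fst did not pass, at 49.0 ± 5.88 CPM in ff and 9.22 ± 6.41 CPM in dd (edgeR adjusted p = 0.0549). Hdc, the histamine-forming enzyme, rose 2.13-fold, while the homeobox genes Hoxa10 and Hoxa11 fell to 0.700 and 0.705 of the ff level. Stromal markers were lower (median −0.71) and epithelial markers higher (1.11) in the same libraries. The calls of Hoxa10 and Hoxa11 were lost without any 1 library, and Hdc kept its call only without ff replicate 2. Without ff replicate 1 no member of this list was called. Areg, an epithelial growth factor induced by progesterone, was at 11.7 ± 3.88 CPM in ff and 3.70 ± 1.22 CPM in dd and did not pass (adjusted p = 0.0593). Ihh at 92.7 ± 34.1 CPM in ff and 108.9 ± 35.8 in dd, and Hand2 at 64.2 ± 10.4 CPM in ff and 56.7 ± 17.7 in dd, did not pass either. Ube3c, a HECT-type ubiquitin ligase gene, had a log2 change of 0.06 (adjusted p = 0.669), and 0 of 22 HECT ligase genes were called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.609). At an unadjusted p under 0.05 there were 2 higher and 2 lower, and DESeq2 called 1 lower.

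**Figure D2:**
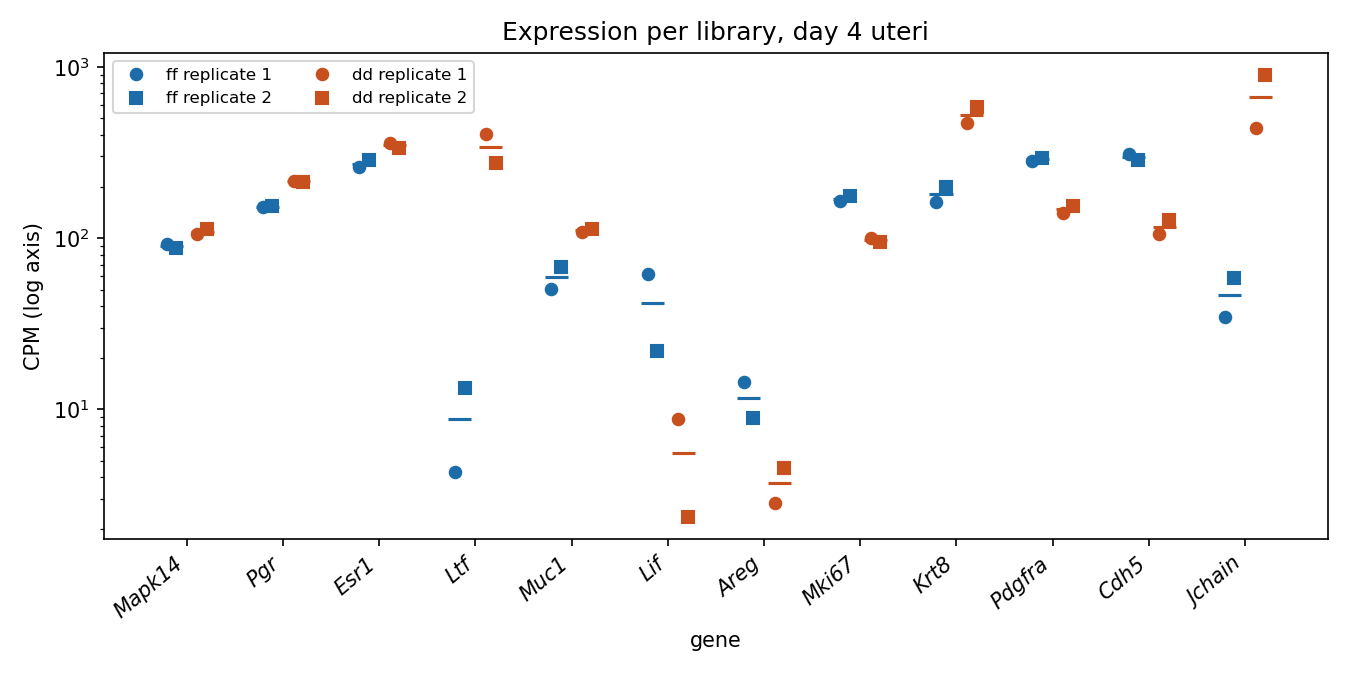
CPM of 12 genes (log axis) in each library, with circles for replicate 1, squares for replicate 2, blue for ff, orange for dd and a bar at each group mean. Mapk14 is slightly higher in both dd libraries, at 109.1 against 89.7 CPM on average, Ltf rises from 8.84 to 340.3 CPM on average, and Lif differs widely between replicates of both groups.

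Among signals for embryo implantation, the prostaglandin synthases Ptgs1 and Ptgs2 rose in dd, from 32.9 ± 9.45 to 144.4 ± 21.8 CPM and from 2.78 ± 0.109 to 19.3 ± 9.83 CPM. Msx2 (log2 1.98), Klf5 (1.02) and Hbegf (0.85) were also higher, in libraries where epithelial markers were higher too (median 1.11). The call of Hbegf was lost without any 1 library, and Klf5 kept its call only without dd replicate 1. Socs3, a feedback inhibitor of cytokine signalling, was lower at 16.3 ± 2.67 against 52.7 ± 13.2 CPM. In all, 5 of 17 members were higher and 1 lower (5 and 3 adjusted over the list alone). The list as a whole did not pass camera (adjusted p = 0.354). It passed fry (adjusted p = 0.0469, up), which does not compare a list with other genes. Lif, the cytokine required for implantation, had 2040 and 682 counts in ff and 208 and 71 in dd, a log2 change of −2.92 that did not pass edgeR's quasi-likelihood test (SE 0.788, adjusted p = 0.0895). It passed with DESeq2 (adjusted p = 0.0447), and the authors' deposited table gives it a fold of 0.133 with an unadjusted p of 6.05e-09. Ptgs2 had a log2 change of 2.79, or 2.15 without dd replicate 2, and did not pass without ff replicate 1 (adjusted p = 0.112) or ff replicate 2 (adjusted p = 0.0656), and without ff replicate 1 no member of the list was called.

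Other signalling lists held few called genes. In the prostaglandin list the receptor genes Ptgfr (log2 −1.13) and Ptger3 (−0.95) were lower and 0 of 13 members higher (3 and 3 adjusted over the list alone), with a median of −0.31, a mean of 0.00 and a camera adjusted p of 0.733 pointing down. Spred2 (0.71) and Fgf18 (2.25) were higher among 17 genes of FGF and ERK signalling (3 adjusted over the list alone, camera adjusted p = 0.545). Fzd4 (−0.64) was the only call among 18 WNT genes (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.174), and this list passed without ff replicate 2 (adjusted p = 0.0198). In the p38 pathway without Mapk14, the kinase genes Mapk13 (1.15), Map2k6 (1.36) and Mapkapk3 (1.04) were higher and Rps6ka5 (−0.92) lower among 24 members (6 and 1 adjusted over the list alone). This list did not pass (median 0.13, camera adjusted p = 0.248), and epithelial markers were higher (median 1.11) in the same libraries. Mapk13 (chromosome 17, 28769297 to 28780233) lies close to the targeted gene Mapk14, and whether its position matters was not tested. Without ff replicate 1 or dd replicate 2 none of these pathway members was called. Immediate early genes fell as a list (median −1.06, camera adjusted p = 0.0136; adjusted p = 0.646 with an estimated correlation), although Myc (−0.88) was the only member of 14 to pass (1 higher and 7 lower adjusted over the list alone), and stromal markers were lower (median −0.71) and epithelial markers higher (1.11) in the same libraries. Fos, at 1514 and 590 counts in ff and 113 and 235 in dd, did not pass (adjusted p = 0.0562), and the list call was lost without dd replicate 1 (adjusted p = 0.14). Of 4 tested decidual markers none was called by edgeR (1 lower adjusted over the list alone, median −0.46, camera adjusted p = 0.564; 0.0288 without ff replicate 2), with Tdo2 at 3.26 ± 1.84 CPM in ff and 0.610 ± 0.0245 CPM in dd. At an unadjusted p under 0.05 there were 1 higher and 2 lower, and DESeq2 called 2 lower.

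Markers of tissue compartments moved apart, in libraries where red cell and oviduct markers were also higher (medians 1.68 and 0.40). Epithelial genes rose as a list, with all 17 members above 0 and 7 called higher (14 adjusted over the list alone). Their median log2 change was 1.11 (camera adjusted p = 7.75e-07; adjusted p = 0.607 with an estimated correlation). The keratin gene Krt8 rose from 180.0 ± 25.9 to 525.5 ± 77.5 CPM. Krt19 rose 7.63-fold from 92.2 ± 63.6 to 703.3 ± 119.0 CPM. Its ff libraries differed, with 1571 and 4273 counts, and its fold was 5.13 without ff replicate 1 and 14.9 without ff replicate 2. Cdh1, the epithelial cadherin gene, rose 1.94-fold. Stromal and matrix genes fell, with 6 of 25 called lower and 0 higher (8 lower adjusted over the list alone) and a median of −0.71 (camera adjusted p = 4.39e-06; adjusted p = 0.607 with an estimated correlation). Among them, fibronectin (Fn1) went from 1176 ± 36.5 to 576.5 ± 14.6 CPM and Pdgfra, a receptor of stromal fibroblasts, from 288.3 ± 9.98 to 147.1 ± 9.99 CPM. Endothelial genes fell, with 10 of 12 called lower (11 adjusted over the list alone) and a median of −0.94 (camera adjusted p = 9.23e-06; adjusted p = 0.607 with an estimated correlation), including the angiopoietin receptor gene Tek (−1.47) and Cdh5 (−1.36), the cadherin of vessel walls. Muscle genes of the myometrium did not pass (median 0.23, camera adjusted p = 0.46; 0.00154 without dd replicate 2), with the oxytocin receptor gene Oxtr the only call at 44.7 ± 25.3 against 7.16 ± 0.915 CPM (log2 2.64, or 1.91 without dd replicate 1; 1 adjusted over the list alone). Without ff replicate 1, ff replicate 2, dd replicate 1 and dd replicate 2 in turn, 1, 9, 5 and 1 epithelial members were higher, 0, 6, 7 and 1 stromal members lower, and 1, 8, 4 and 3 endothelial members lower. All 3 list calls were kept in these fits, with adjusted p up to 0.000268.

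Proliferation genes were lower as a list, with 6 of 28 members called lower, 0 higher (the same 6 adjusted over the list alone) and a median of −0.49 (camera adjusted p = 6.76e-06; adjusted p = 0.607 with an estimated correlation). Stromal (median −0.71), endothelial (−0.94) and macrophage (−0.85) markers were lower and epithelial markers (1.11) higher in the same libraries. Mki67 fell from 170.0 ± 8.09 to 97.9 ± 3.43 CPM (log2 −0.80, adjusted p = 0.0232), and the mitotic motor genes Kif11 and Kif20a fell by 0.96 and 0.82 on the log2 scale. Mki67 did not pass without ff replicate 1 (adjusted p = 0.0655), dd replicate 1 (0.0571) or dd replicate 2 (0.0724), and leaving out any of these 3 libraries left no member of the list called. In the uterine gland list, Spink1 was the only call among 6 tested genes (1 higher and 1 lower adjusted over the list alone). Prss29, a gland protease gene, had 4319 and 10 counts in the ff libraries and 0 in both dd libraries and did not pass (adjusted p = 0.182). The median of this list was 0.11, whether Prss29 was placed at its fitted value or its bound, its mean with the fitted value of Prss29 was −2.72, and camera pointed up (adjusted p = 0.931).

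**Figure D3:**
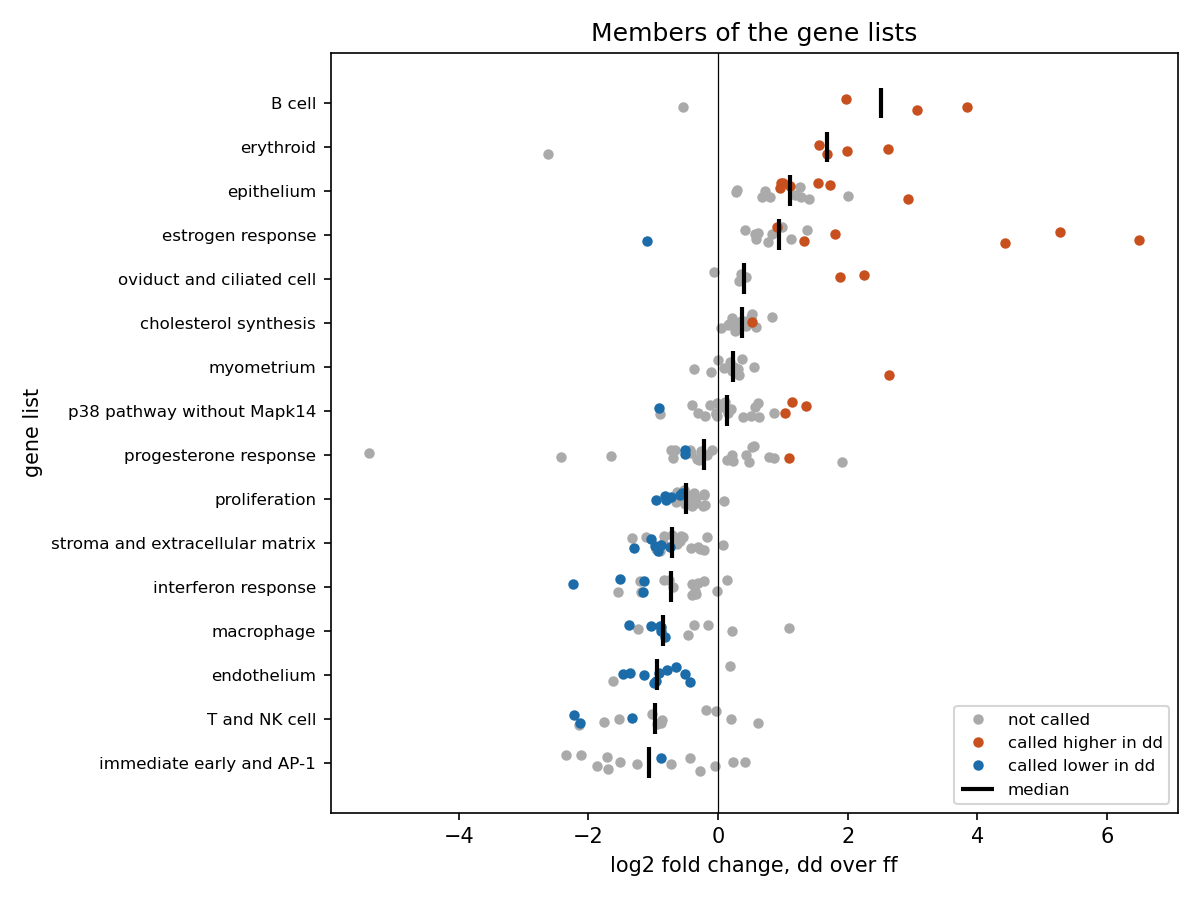
Log2 fold change of dd over ff (horizontal axis) of the tested members of 16 gene lists (vertical axis), with called members in orange (higher) or blue (lower), others in grey and a black bar at each median. Medians run from −1.06 for immediate early genes to 2.52 for the B cell list, with epithelium at 1.11 and endothelium at −0.94.

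Immune genes also moved in both directions, in libraries where stromal (median −0.71) and endothelial (−0.94) markers were lower and epithelial markers (1.11) higher. Transcripts of T and NK cells were lower as a list (median −0.98, camera adjusted p = 0.00129; adjusted p = 0.607 with an estimated correlation), with 3 of 14 called lower (7 adjusted over the list alone). These were the perforin gene Prf1, from 10.2 ± 2.22 to 2.18 ± 0.0922 CPM, Eomes (log2 −2.13) and Nkg7 (−1.33). Macrophage genes fell (median −0.85, camera adjusted p = 0.00129; adjusted p = 0.607 with an estimated correlation), with 6 of 12 called lower (1 higher and 9 lower adjusted over the list alone). The complement genes C1qa, C1qb and C1qc fell by 0.90, 0.82 and 0.88 on the log2 scale. Interferon-responsive genes fell (median −0.73, camera adjusted p = 0.00123; adjusted p = 0.607 with an estimated correlation), with 4 of 18 called lower (6 adjusted over the list alone), namely Ifit3 (−2.24), Cxcl10 (−1.51), Gbp3 (−1.15) and Ifit2 (−1.15), and this list call was lost without dd replicate 1 (adjusted p = 0.0975). Without ff replicate 1 no member of these 3 lists was called. Without dd replicate 1 there were 3 T and NK cell, 1 macrophage and 3 interferon members lower, and without dd replicate 2 there were 1, 0 and 5. Of 12 inflammatory cytokine genes, Csf3 was higher at 29.5 ± 2.46 against 2.998 ± 1.44 CPM (log2 3.30, or 3.89 without ff replicate 2; 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.345). Of 3 neutrophil genes 0 were called by edgeR (1 lower adjusted over the list alone, median −0.75, camera adjusted p = 0.152; 0.00209 without ff replicate 1), with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2.

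Of 162 tested immunoglobulin segments 79 were called higher in dd and 0 lower by edgeR, 137 and 0 at an unadjusted p under 0.05, and 120 and 0 by DESeq2. Immunoglobulin transcripts took 0.049% and 0.076% of counts in the ff libraries and 0.396% and 0.961% in the dd libraries. Jchain, the joining chain gene of secreted antibodies, rose from 46.6 ± 16.8 to 667.0 ± 322.0 CPM (log2 3.84, or 3.24 without dd replicate 2; adjusted p = 0.0246), a call lost without ff replicate 1 (adjusted p = 0.0763). The heavy chain gene Ighg2c had 0 and 2 counts in ff and 974 and 3755 in dd, a ratio of 2826 (95% counting interval 782 to 23339). Variable segments Igkv9-124, Igkv5-39, Igkv3-5 and Igkv4-90 had no count in ff and were at least 399.9, 362.5, 176.9 and 119.5-fold higher in dd, against a floor of 3 counts over the group. Most of their dd counts came from dd replicate 2. The dd libraries held 187 and 817 counts of Igkv9-124, 133 and 777 of Igkv5-39, 163 and 281 of Igkv3-5 and 65 and 235 of Igkv4-90. Without dd replicate 2 the bounds were 170.0, 120.9, 148.2 and 59.1, and without ff replicate 1 they were 193.3, 175.2, 85.5 and 57.8. Ighv14-2 had 1 count in ff and a ratio of 717 (128.2 to 28367), and Ighv1-80 had 2 and a ratio of 494.7 (136.5 to 4092). Without dd replicate 2 the ratios of Ighg2c, Ighv14-2 and Ighv1-80 were 1328, 471.8 and 271.3. Without the ff library that held their counts they were bounds of at least 973.1, 123.5 and 159.4, and without the other ff library they were 1366, 346.6 and 255.6. None of these 3 genes passed without ff replicate 1 (adjusted p = 0.0687, 0.0545 and 0.0635). In the B cell list, Jchain, Cd79a (3.07) and Cd79b (1.97) were higher among 4 tested genes (3 adjusted over the list alone), with a median of 2.52 (camera adjusted p = 0.0702; 0.0332 without dd replicate 2), while Ighm had a log2 change of −0.54 that did not pass (adjusted p = 0.249). Cd79a had a log2 change of 2.37 without dd replicate 2 and did not pass without it, ff replicate 1 or ff replicate 2 (adjusted p = 0.0509, 0.116 and 0.0723). Cd79b did not pass with upper quartile factors (adjusted p = 0.0505).

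Transcripts of other tissues were measured as a check on what the samples held. Red cell genes were higher as a list (median 1.68, camera adjusted p = 0.00663; adjusted p = 0.607 with an estimated correlation), with 4 of 5 tested called (4 adjusted over the list alone). Hba-a1 rose from 24.5 ± 0.844 to 150.9 ± 29.5 CPM and Hbb-bs 3.20-fold, while Hba-a2, a near-identical copy of Hba-a1, had 205 and 233 counts in ff and 51 and 4 in dd and did not pass (adjusted p = 0.174). Leaving out any 1 library left 1 or 2 red cell genes higher, and Hba-a2 lower without dd replicate 1. Oviduct and ciliated cell genes were higher as a list (median 0.40, camera adjusted p = 0.0136; adjusted p = 0.607 with an estimated correlation), with Ovgp1, an oviduct glycoprotein gene, up from 25.9 ± 1.48 to 123.2 ± 2.01 CPM and Foxj1, the regulator of motile cilia, up by 1.88 on the log2 scale among 6 tested (3 adjusted over the list alone), of which 1 was called when any 1 library was left out. Cholesterol synthesis genes rose slightly as a list (median 0.37, all 16 above 0, camera adjusted p = 0.00129; adjusted p = 0.607 with an estimated correlation), with Hmgcs1 the only call at 1.43-fold (1 adjusted over the list alone), lost when any 1 library was left out, and epithelial markers were higher (median 1.11) in the same libraries. The remaining lists did not pass camera. Star (0.82) was called among 3 ovary genes (1 adjusted over the list alone, median −0.18, mean 0.10, camera adjusted p = 0.701, up), and Cfd (4.35) among 3 adipocyte genes (1 adjusted over the list alone, camera adjusted p = 0.248; 0.0467 without ff replicate 2 and 0.0451 without dd replicate 2; fry adjusted p = 0.0352, up). Without dd replicate 2 Cfd did not pass (log2 3.54, adjusted p = 0.0695). No gene was called by edgeR among 5 of skeletal muscle (1 lower adjusted over the list alone, median −0.46, mean 0.01, camera adjusted p = 0.418, down), 6 of mesothelium (1 and 1 adjusted over the list alone, camera adjusted p = 0.759) or 12 of endoplasmic reticulum stress (0 adjusted over the list alone, camera adjusted p = 0.345). At an unadjusted p under 0.05 these held 1 lower, 1 higher with 1 lower, and 0 genes, and DESeq2 called the same numbers. These 3 lists passed camera without dd replicate 1, at adjusted p of 0.0342, 0.0342 and 0.0428. Of 8 genes of the preimplantation embryo only Elf5 was tested, at 1.79 ± 1.51 CPM in ff and 5.41 ± 1.15 CPM in dd (adjusted p = 0.186).

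The authors' deposited table lists 3153 genes with an unadjusted p under 0.05, of which 1678 have a fold above 1 and 1475 below 1. In the authors' deposited table, Ltf has a fold of 38.5 and Areg a fold of 0.317 with an unadjusted p of 0.000618. Pgr has a fold of 1.41 with an unadjusted p of 0.286 in the authors' deposited table, whereas it passed edgeR's quasi-likelihood test here.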

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

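The settings restricted to protein-coding genes and to library size were chosen after seeing the data; the others were fixed before. No called named gene or list reversed its direction in these settings, and Mapk14 was not called in any (log2 0.20 to 0.34). Counts of changed genes rose without a filter (2947; 1584 higher, 1363 lower), with the DESeq2 Wald test (3001; 1584 and 1417) and with edgeR's exact test (3051; 1590 and 1461). They fell to 10 (9 and 1) at an adjusted p under 0.01 and to 964 (566 and 398) when a 2-fold change was also asked. The cause was not tested for the filter and the tests, while the last pair follow from their construction. Leaving out 1 library gave 90 to 1198 changed genes, 62 to 726 higher and 28 to 472 lower, from fewer samples. Other settings gave 1232 to 1771. Upper quartile factors gave 748 higher and 830 lower (47.4% higher). Library size alone gave 751 higher and 1020 lower (42.4% higher against 53.9%) and gave a median of all genes of −0.082 on the log2 scale, against 0.002 with TMM. Of 31 lists 12 passed (5 up, 7 down), 0 with an estimated correlation and 6 with fry (4 up, 2 down; the implantation and adipocyte lists passed fry but not camera), for which the cause was not tested. Libraries with the same replicate number shared only the number (correlation of deviations 0.013, with 2 pairs). With the replicate block 1531 genes changed (878 higher, 653 lower), 1179 of them among the 1554, and the B cell list passed (adjusted p = 0.021). Among named genes, 8 lost their call with the block, Pgr among them (adjusted p = 0.0652), and 9 gained one. Of the named genes, 68 lost their call without ff replicate 1, 25 without ff replicate 2, 43 without dd replicate 1 and 53 without dd replicate 2. With 2 libraries per group, 2-fold changes were often missed in simulated counts with 200 of 18162 genes changed. There 54% of 2-fold increases and 36% of decreases to a fold of 0.5 were found. More genes were called in these data, so the shares found here may differ.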

Other observations

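The calls of single genes by edgeR and the camera test of the myometrial list were planned, while the family tests, the window scan, the permutation and Fisher's exact tests and the weighing of explanations were chosen after the results were seen, as were the genes named other than Fn1, Jchain, Ighm, Cd79a and Mapk14. Among the called protein-coding genes that gained most CPM in the libraries labelled dd, Cbr2, a carbonyl reductase gene, rose 16.4-fold from 51.5 ± 34.5 to 843.1 ± 231.0 CPM (SD, n = 2; 31.1-fold without ff replicate 2), the lipoxygenase gene Alox12e 8.73-fold to 742.9 ± 59.6 CPM, the branched-chain aminotransferase gene Bcat1 7.83-fold to 776.6 ± 18.7 CPM (5.12-fold without ff replicate 1 and 16.6-fold without ff replicate 2), Cndp2 4.501-fold and the secretory coat gene Sec23b 3.86-fold. The collagen IV gene Col4a1 lost most, from 1426 ± 73.1 to 615.0 ± 110.0 CPM, followed by Fn1, by the intermediate filament gene Vim, from 1105 ± 67.5 to 579.3 ± 38.3 CPM, and by Ctla2a, from 562.5 ± 167.0 to 112.8 ± 44.7 CPM. Further down that order, Col4a2 went from 837.9 ± 77.9 to 410.4 ± 72.1 CPM, Col15a1 fell by 1.26 on the log2 scale, and the apelin receptor gene Aplnr fell from 191.7 ± 49.5 to 42.2 ± 10.2 CPM. Of these genes only Alox12e was called whichever library was left out, and the others missed the threshold without at least 1 library (adjusted p up to 0.112).

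Of 181 families of protein-coding genes with a shared symbol stem and at least 10 tested members, 13 passed camera at its preset correlation and 0 with an estimated correlation (adjusted p = 0.982 for each). The lower families included Ifi (9 of 15 called lower and 1 higher, median −1.54, camera adjusted p = 9.5e-05), collagens (6 of 41 lower, median −0.63, camera adjusted p = 0.000572) and Adamts proteases (7 of 18 lower, median −0.84, camera adjusted p = 0.00601). Of the Ifi calls, 8 of the lower ones and the higher one lie in the chromosome 1 window described next, so both are 1 observation. The 5 Ifi members outside it had a median of −0.35, with 1 lower. Keratins were higher (9 of 20 called and 5 below 0, median 0.94, camera adjusted p = 0.00601), as were subunits of mitochondrial complex I, with 10 of 10 Ndufb genes above 0 but 1 called (median 0.41, camera adjusted p = 0.0297) and 12 of 14 Ndufa genes above 0 but 4 called (median 0.37, camera adjusted p = 0.0366). In the same libraries epithelial markers were higher (median 1.11) and stromal (−0.71) and endothelial (−0.94) markers lower.

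Called genes were crowded on chromosome 1 between 170 and 175 Mb (mm10), where 25 of 86 tested genes were called (6 higher, 19 lower), against 7.9% elsewhere. Immunoglobulin segments left out, no fullest window of 5 Mb in 10000 random placements of the calls was as extreme (permutation p = 0.0001, the smallest these can give). Ifi202b had 1 count in each ff library and 346 and 290 in dd, while Ifi206 fell by 5.78 and Olfml2b by 2.09 on the log2 scale, and the Fc receptor gene Fcer1g fell by 1.53 (not called without ff replicate 1, adjusted p = 0.0501). For a haplotype block of another mouse strain, 20% of called genes in the window (5 of 25, 3 of them Ifi genes, exact 95% interval 6.8 to 40.7) had a log2 change of at least 4 either way, against 7.1% of other called genes (1 of 2 tests, Fisher's exact test, two-sided p = 0.0313). It cannot be told apart from coordinate change of the neighbouring interferon-inducible, Fc receptor and SLAM families or from an effect of the genotype, since that interval includes the share outside, and 15.3% of the window's other genes were called (9 of 59, exact 95% interval 7.2 to 27.0, Fisher's exact p = 0.0499) in a window picked for its calls.

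Epithelial genes were higher while stromal and endothelial genes were lower in dd. A smaller share of stromal cells alone would raise epithelium and endothelium alike, but their medians differed by 2.05 on the log2 scale (1.11 against −0.94). The difference was 1.61 to 2.29 over the 4 pairs of a dd with an ff library, which share libraries. The permutation p over genes was 2e-05 (adjusted 5e-05), too small since genes of a list are not independent. The directions of these lists were known when the permutation tests were chosen, so this p and those below add no support. A larger share of epithelium would lower endothelium and myometrium alike, but these differed by −1.17 (−0.94 against 0.23, permutation p = 0.00024, adjusted 0.0004; −1.41 to −0.65 over the pairs). A smaller share of stroma with its vessels cannot be told apart from a change within cells, since epithelium exceeded myometrium by 0.88 (permutation p = 0.00794, adjusted 0.00992) but by 0.21 to 1.6 over the pairs, and the myometrial list was itself higher without dd replicate 2 (camera adjusted p = 0.00154, against 0.46 with all libraries). Changes in several compartments at once stay open, as does the genotype itself. The genotype is untested, since its label and the group are the same split of these libraries. Mapk14 counts do not bear out the labels, but counts over the whole gene cannot show the loss of a few exons.

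Immunoglobulin transcripts were higher in dd, with Igha at 264.2 ± 82.8 CPM in ff against 2893 ± 1620.0 CPM and Igkc at 188.9 ± 39.4 CPM in ff against 2544 ± 1420.0 CPM (log2 3.45 and 3.75, or 2.73 and 3.03 without dd replicate 2; neither passed without ff replicate 1, adjusted p = 0.101 and 0.0918). Circulating B cells of blood left in the tissue would bring Ighm together with Cd79a, but Ighm had a log2 change of −0.54 (95% interval −1.23 to 0.14) against 3.07 for Cd79a (1.87 to 4.26; 2.37 without dd replicate 2). Ighm lies near Ighg2c on chromosome 12, where another haplotype stays open as given below, so Ighm alone cannot settle this. Red cell genes were higher too, so blood itself is not excluded. Another immunoglobulin haplotype against the reference would by itself leave Jchain, outside these loci, unmoved. Jchain rose by 3.84 on the log2 scale (edgeR adjusted p = 0.0246), or by 3.51 without ff replicate 1. This cannot exclude such a haplotype acting beside more antibody-secreting cells. Ighg2c had 0 and 2 counts in ff against 974 and 3755 in dd, although Igkc had 5359 and 6751 in ff. For segments with almost no count in ff a haplotype stays open. More antibody-secreting cells in the tissue stay a candidate explanation, with Derl3 (7.53-fold, not called without ff replicate 1 or 2, adjusted p = 0.0857 and 0.0537) and the plasma cell attractant gene Ccl28 (7.84-fold) also higher and Mzb1 short of the threshold (adjusted p = 0.0502).

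Outside immunoglobulin segments, 108 called genes differed by at least 4 on the log2 scale, 76 of them higher and 32 lower in dd. Of the 108, 26 (24.1%) were pseudogenes, against 2.8% of the other called genes. The sets were not matched for expression, and a gene with few counts is called only if its change is large. The difference in shares therefore says nothing about pseudogenes as such. Within 10 Mb of Mapk14, 37 of 458 genes (8.08%, exact interval 5.8 to 11) were called, against 8.03% elsewhere. AC165951.1, with no count in ff and 370 and 440 in dd, and Mapk13 are among these called genes. A share over 458 genes cannot show an effect limited to a few genes near Mapk14, so such an effect stays open. Among genes with at least 5 CPM on average, the ff libraries differed at least 4-fold in 54 of 12313 genes and the dd libraries in 50 of 12334. The progesterone-induced gene Cyp26a1 was among these in ff, with 7522 and 101 counts, against 72 and 75 in dd.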
